A study of Mus musculus with 2 samples.

How the data were processed

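RNA from 2 samples of EB5 mouse ES cells that received Klf4 siRNA and a puromycin-resistance plasmid was compared with a common reference on 2 two-colour Agilent arrays. Per the labels, the ES cell RNA carried Cy3 and the reference, a pool from 11 mouse cell lines, carried Cy5 on both arrays, after linear amplification. Both samples form 1 group, siKlf4 ES cells (n = 2), numbered 1 and 2 in the labels; whether the numbers stand for cultures, siRNAs or hybridisations is not given in the sources used here. No sample without Klf4 siRNA and no dye swap was among the samples. Each array had 22132 spots, of which 21052 were gene probes and 1080 controls, with 162 negative control spots.

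Per the file headers, the authors' scanner files were made with Agilent Feature Extraction A.7.5.1 and hold intensity values in arbitrary units: mean spot signals and local background signals as scanned, and processed signals after local background subtraction and LOWESS dye normalization by that software. The deposited log10 ratio of each spot is that of the red over the green processed signal, checked against those signals. The deposited series table holds log10 values whose making is not given in the sources used here. From the values, each equals the mean log10 red processed signal of both arrays minus the log10 ratio of that array, within 2e-04 for 99.62% and 99.61% of 21052 probes, so it carries the same ratios as the processed signals and is not centred (medians 2.918 and 2.921).

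Mean signals were corrected with limma 3.58.1 in R 4.3.3 by normexp on the local background median with an offset of 50, then normalised by loess within each array, with control spots at weight 0. Ratios are given as log2 of ES cells over reference. Spots marked as outliers by the scanner software were left out, which removed 24 probes and kept 21028. The planned filter, the software's well-above-background flag in the same channel on both arrays, removed 0 probes: it was set for 100% of gene probes and also for 100% of negative control spots in the ES channel, and for 88.9% and 91.4% of negative control spots in the reference. After the data were seen, a probe was therefore also classed as above or not above the 95th percentile of the negative control spots, at 155 and 178 units above background in the ES channel and 40.9 and 58.4 in the reference. A fold for a probe below this limit in 1 channel on both arrays is given as a bound, with that channel raised to the limit before background correction and the probe's loess correction kept. Precision is limited by the number of arrays.

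Probes were named through their RefSeq accessions with a table of mouse RefSeq genes, used for names only, since the files give accessions and not symbols: 10422 probes received 1 symbol, for 10149 genes, and 10630 received none and were counted but not named. For genes with several probes the brightest was used. Of 241 such genes, 24 had probes that differed by more than 1 in log2 ratio, and 28 had probes past the threshold in opposite directions.

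Mean log2 ratios were tested against 0 with limma (lmFit, eBayes, 1 residual and 4.24 prior degrees of freedom), with Benjamini-Hochberg adjusted p under 0.05 over all probes. Gene lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the 28 lists; camera with an estimated correlation and fry served as alternatives. The difference between arrays and the spread of each channel (after loess and Aquantile) are values without a test. Tests, gene lists, the first set of other settings and the rule for named genes were fixed before the data were examined. By that rule, Klf4, Pou5f1, Sox2 and Lefty1 were always named, Klf4 first. Against the reference, the 10 genes with the highest and the 10 with the lowest mean log2 ratio were named, among probes past the threshold with the same sign on both arrays, 1 symbol, well above background and not saturated. Up to 4 members of each list were named, those past the threshold with the largest absolute log2 ratio first and those with only a bound after them, and between arrays the 10 genes with the largest absolute difference. Which members came after the others was decided by the negative control limit, so that part of the rule was set after the data were seen. Of the genes this rule gives, 2 are not named in the text or the plots, and the counts and list results still include them. Genes outside the rule were chosen after their values were seen: the Hprt gene and its neighbours, list members with opposite sign, not passed or given as a bound, and the next 20 genes in each direction.

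The calling was tested on simulated data with 21028 probes and the spread of these arrays: of 200 changed probes per simulation (10 simulations), 17.8%, 95.4% and 99.8% were called at log2 changes of 0.25, 0.5 and 1, and 6.8% of calls were unchanged probes. The simulated unchanged probes were centred on 0, without any dye, background or position effect. The 6.8% is therefore not the rate of false calls on these arrays, where 115 of 162 negative control spots passed. Nor do the called percentages carry over, since 63.1% of probes passed on these arrays, which loosens the Benjamini-Hochberg limit. The smallest absolute log2 ratio that passed there was 0.106. Of random lists 0.3% were called, and of lists of 22 genes shifted by 1, 100% (100 draws). Random lists hold unrelated genes, so the 0.3% does not carry over to lists of genes that vary together.

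The first set of other settings comprised no background correction, an offset of 10, median centring in place of loess, the software's processed signals, the series table, no filter or the flag in both channels, outlier spots kept, saturated spots left out, a variance trend, adjusted p under 0.01, the mean of a gene's probes, both other list tests, each array alone, and quantile or median scaling of the channels. Settings chosen after the data were seen were background from the negative control spots, filters on the negative controls in the same channel or in both, the housekeeping list without Hprt, removal of a trend over brightness and position (loess span 0.1), and a limit on the log2 ratio from the negative controls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.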

Results

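RNA abundance was measured on 2 two-colour oligonucleotide arrays in EB5 mouse embryonic stem (ES) cells, a feeder-free line, that had received Klf4 siRNA together with a plasmid carrying puromycin resistance. Cells were grown for 24 h after transfection and for another 24 h in puromycin before RNA was extracted. The ES cell RNA was labelled with Cy3 and hybridised against a common reference labelled with Cy5, a pool of RNA from 11 mouse cell lines of embryo, fibroblast, kidney, liver, macrophage, lymphocyte, mammary, muscle, skin and testis origin. The 2 arrays form 1 group (siKlf4 ES cells, n = 2), and the labels do not say whether they are separate cultures. Each array held 21052 gene probes. The median probe in the ES channel lay 308 and 355 intensity units above its local background, against 129 and 138 for the median negative control spot, and in the reference channel 246 and 264, against 28.5 and 32.3. The series title concerns joint activation of the Lefty1 promoter by Klf4, Oct3/4 and Sox2, but no ES cells without Klf4 siRNA were among the samples. The arrays therefore compare siKlf4 ES cells with a pool of other cell types and carry no estimate of the siRNA's effect.

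Klf4, the transcription factor targeted by the siRNA, was 1.42-fold higher in the siKlf4 ES cells than in the reference pool, with a log2 ratio of 0.51 ± 0.11 (SD, n = 2) and single-array values of 0.43 and 0.59 (limma, adjusted p = 0.000463). The other genes of the title stood far higher above the pool, where their reference signals were 113 to 242 units against 1518 and 1603 for Klf4. In the ES channel the Klf4 probe was brighter than those of Pou5f1 (1469 and 1762) and Lefty1 (1246 and 1505) and dimmer than that of Sox2 (10743 and 13668). Sox2, a partner of Oct3/4 in ES cells, had a log2 ratio of 5.69 ± 0.14, equal to 51.7-fold. Lefty1, a secreted inhibitor of Nodal signalling, reached 3.14 ± 0.022 or 8.84-fold, and Pou5f1, which encodes Oct3/4, 2.86 ± 0.053 or 7.24-fold. The Klf4 value was slightly under the largest absolute log2 ratio seen at a negative control spot, 0.52, although its probe was far brighter than those spots (1826 and 2543 units in the ES channel), whereas those of Sox2, Lefty1 and Pou5f1 were several times larger. Without background correction, which leaves the scanner offset in, Sox2 stood at 4.34, Lefty1 at 1.65 and Pou5f1 at 1.68.

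The largest ratios in either direction are given for single genes, which stand for no tested group. The highest gene was Tdgf1, the Nodal co-receptor Cripto, at 5.98 ± 0.066 (SD, n = 2) or 63.1-fold, although a dimmer Tdgf1 probe gave 2.36 and the mean of both probes was 4.17. After Sox2 came Zfp42 (Rex1) at 5.01 ± 0.21 and the Akt cofactor Tcl1 at 4.43 ± 0.031. Morc1, needed for transposon silencing in male germ cells, stood at 4.38, the glycine-cleavage enzyme Gldc at 4.34 and the uridine phosphorylase Upp1 at 4.29. The orphan nuclear receptor Nr0b1 (4.03) and the junctional adhesion molecule Jam2 (3.91) were also among the 10 highest. The lowest gene was the immediate-early transcription factor Egr1 at -5.32 ± 0.0026, 39.8-fold below the reference. Without background correction Egr1 stood at -3.82 and Lhfpl1 was lower, at -4.08. The small matrix proteoglycans Bgn and Dcn stood at -4.78 ± 0.062 and -4.64 ± 0.019, and Cavin2 and Cav1, components of caveolae, at -4.68 and -4.62. Complement C3 (-4.49), the matrix protein gene Efemp1 (-4.44) and Lhfpl1 (-4.35) were also among the 10 lowest. The lysosomal protease gene Ctss and the acute-phase gene Saa3 were not above the negative control spots in the ES cells on either array, so the reference exceeded them at least 22.7-fold and at least 19.6-fold, bounds that hold only with background correction.

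**Figure D1:**
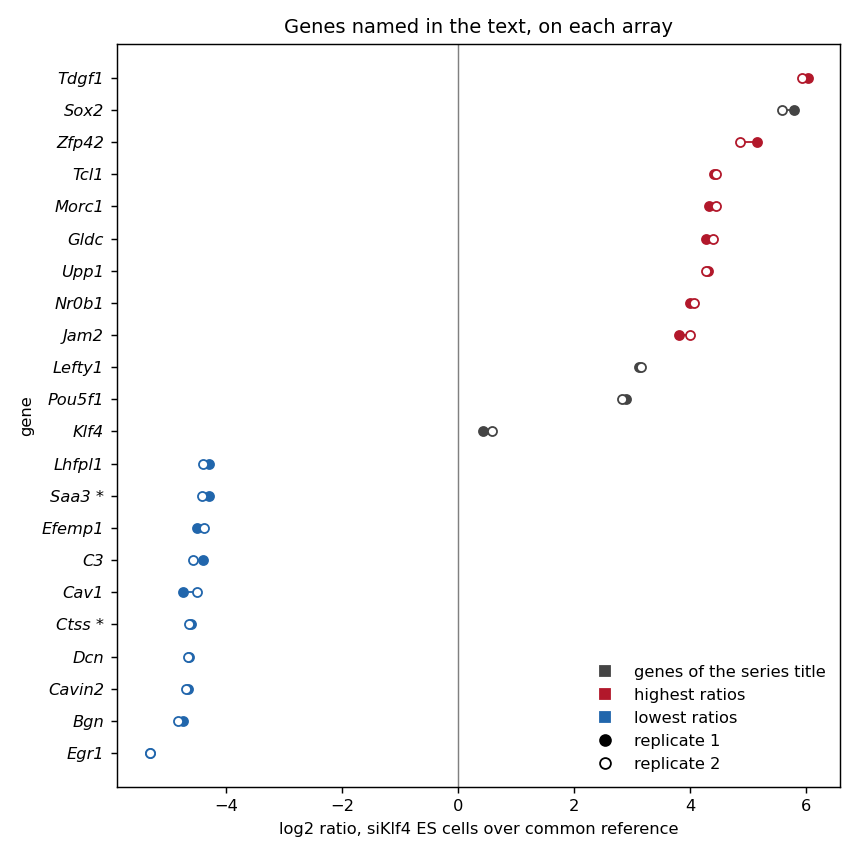
Log2 ratio of siKlf4 ES cells over the common reference (x axis) for the genes of the series title and of the highest and lowest ratios named in the text (y axis), with replicate 1 as filled and replicate 2 as open circles; an asterisk marks genes not above the negative control spots in the ES cells. Tdgf1 (5.98) and Egr1 (-5.32) lie at the ends, and Klf4 (0.51) is the gene closest to 0.

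Over all 21028 probes tested, 1068 were at least 2-fold higher and 1092 at least 2-fold lower in the siKlf4 ES cells, with an adjusted p under 0.05 and the same sign on both arrays. Of these, 1034 of the higher and 905 of the lower probes lay above the negative control spots in both channels on both arrays. Another 147 of the lower probes were not above them in the ES channel on either array, and 16 of the higher probes were not above them in the reference. Without a limit on size, 6654 probes were higher and 6612 lower, 63.1% of those tested. That count needs care, because 115 of the 162 negative control spots, which carry no mouse sequence, also passed at the same p. Of these spots, 0 reached 2-fold. Of 1610 probes above the negative control limit in neither channel on either array, 975 passed. Members of the gene lists below are counted at this same threshold. The 63.1% covers both directions, so a count of higher members is to be read against 6654 of 21028 probes. A count of lower members is to be read against 6612 of 21028. A passing log2 ratio within the range of the negative control spots, up to 0.52, may be technical. Restricted to log2 ratios beyond every negative control spot, a limit chosen after the data were seen, the counts over all probes were 2552 higher and 2273 lower. Without background correction the 2-fold counts were 469 and 440, and with median centring in place of loess 849 and 1245, so their near-even balance depended on the scaling. With both arrays of the same dye orientation a dye effect stays in every ratio. The p-values of single probes rest on the spread between these arrays, largely pooled over probes, which may be technical. Those of the camera test with a preset correlation compare the genes of a list with all other genes. They treat genes as the units and do not measure a spread between samples.

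Pluripotency genes were the group that stood highest above the reference. Of 22 measured members, 21 were higher, 0 lower and 1 did not pass, with 17 at least 2-fold higher and a median log2 ratio of 3.11 (1.86 without background correction); the counts were the same adjusted over the list alone. Besides Tdgf1, Sox2, Zfp42 and Tcl1, the group held Klf2 (3.37) and Klf5 (1.95), relatives of Klf4. Esrrb and Nr5a2 were counted as higher at 0.27 and 0.36, but neither lay above the negative control spots in either channel, and Fgf4 stood at 0.00. The list was called by limma's camera test with a preset correlation (adjusted p = 6.86e-09) and by fry, which does not compare a list with other genes (adjusted p = 0.0149), but not by camera otherwise (adjusted p = 0.611 with an estimated correlation). That last value was the smallest for any of the 28 lists, so no list call was kept with an estimated correlation. The smallest unadjusted p of that camera test was 0.0953. With 2 arrays it has only 1 residual degree of freedom and so very little power. Its lack of calls, here and for the lists below, therefore does not show that correlation within a list accounts for the other calls.

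Genes of DNA replication and mitosis were higher as well, with 16 of 17 measured members higher, 0 lower and 1 not passed (17 higher adjusted over the list alone). Their median was 1.03, about 2-fold. Ccne1, the cyclin of entry into S phase, stood at 2.14 ± 0.10 and the mitotic cyclin Ccnb1 was 2.83-fold higher, while the replicative helicase subunits Mcm6 and Mcm3 stood at 1.36 and 1.35. The list was called at an adjusted p of 1.88e-06 (adjusted p = 0.611 with an estimated correlation). Regulators of the G1 phase lay on the other side, with 10 of 14 lower, 2 higher and 2 not passed, the same adjusted over the list alone, and a median of -0.94 (-0.81 with members at their bound, -0.32 without background correction). The CDK inhibitors Cdkn2c (-1.95) and Cdkn1a (-1.63) and the cyclin gene Ccnd1 (-1.21) were lower, and the CDK inhibitor Cdkn1c was higher (1.21). That list passed at an adjusted p of 0.00735 (adjusted p = 0.611 with an estimated correlation).

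DNA methylation and chromatin genes were higher in 7 of 9 cases, with 0 lower and 2 not passed, the same adjusted over the list alone (median 1.03; adjusted p = 0.00236, and adjusted p = 0.611 with an estimated correlation). The de novo methyltransferase Dnmt3b stood at 3.13 ± 0.21, its cofactor Dnmt3l at 2.58 ± 0.060, the Polycomb subunit Eed at 2.07 and the helicase Hells at 1.78. Among germ cell genes, 9 of 12 were higher, 1 lower and 2 not passed, the same adjusted over the list alone, at a median of 0.78 (0.76 with members at their bound). Stra8, a retinoic acid target at meiotic entry, stood at 2.49, Tex14 at 1.20 and Mael, a piRNA pathway gene, at 0.68, while Dmrt1 was lower (-0.12). Piwil2 and Mov10l1, counted as higher, lay above the negative control spots in neither channel. In the reference, 6 of the 12 were not above the negative control spots, among them Kit, which was at least 5.79-fold higher in the ES cells, a bound computed with background correction. The germ cell list passed at an adjusted p of 0.00661 (adjusted p = 0.611 with an estimated correlation, range over the alternatives 0.00188 to 0.611). It did not pass in camera among probes above the negative controls in both channels (adjusted p = 0.251), a filter chosen after the data were seen. That filter left out Tdrd1 and the 6 members not above these spots in the reference, Kit among them, so 0.251 belongs to a shorter list.

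Fibroblast and matrix genes were the lowest group. Each of the 18 measured members was lower, 0 were higher and 15 were at least 2-fold lower, with a median of -2.21 (-1.96 with members at their bound, -1.12 without background correction) and the same counts adjusted over the list alone. After Bgn and Dcn, the intermediate filament gene Vim stood at -3.81 ± 0.10 and the matrix gene Fbln2 at -2.95 ± 0.10. The collagen cross-linking enzyme gene Lox was at least 12.7-fold higher in the reference, a bound computed with background correction. The list was called at an adjusted p of 1.27e-08 (adjusted p = 0.611 with an estimated correlation).

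Genes of antigen presentation, the interferon response and macrophages were also lower. All 7 measured genes of the MHC class I pathway were lower, 0 higher, at a median of -1.72 (-0.74 without background correction), led by the immunoproteasome subunit Psmb8 (-3.84) and the light chain B2m (-3.81), with Psmb9 at -1.72 and H2-Q1 at -1.66 (adjusted p = 0.000311, and adjusted p = 0.611 with an estimated correlation). Interferon response genes were lower in 16 and higher in 3 of 19 cases at a median of -0.39; Usp18, a brake on interferon signalling, stood at -3.09, Irgm1 at -1.35, Oasl1 at -1.28 and Ifit2 at -1.17 (adjusted p = 0.00206, and adjusted p = 0.611 with an estimated correlation). Of 12 macrophage markers, 10 were lower and 2 higher at a median of -1.24 (-1.82 with background taken from the negative control spots), with Spp1 at -3.80, Lgals3 at -3.57, Tyrobp at -2.12 and Cd14 at -1.96 (adjusted p = 0.00564, and adjusted p = 0.611 with an estimated correlation). Counts in these 3 lists were the same adjusted over the list alone.

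Hox and housekeeping genes were lower by narrow margins. Of 17 Hox genes, 11 were lower, 1 higher and 5 not passed, the same adjusted over the list alone, at a median of only -0.13. Hoxc6 (-1.91), Hoxa10 (-1.76) and Hoxa7 (-1.76) were lower by more than 2-fold, though not without background correction (-0.98, -0.85 and -0.86), and Hoxb6 stood at -0.37 (adjusted p = 0.0429, and adjusted p = 0.611 with an estimated correlation). Among 9 housekeeping genes, 7 were lower, 1 higher and 1 not passed, the same adjusted over the list alone, at a median of -0.49, with Actb at -1.06, Pgk1 at -0.99 and Tfrc at 1.29 (adjusted p = 0.0475, and adjusted p = 0.611 with an estimated correlation). Hprt, singled out after its values were seen, was above the negative control limit in the ES cells on only 1 array, so its ratio is uncertain (-4.29, or -2.34 without background correction), and without it the list did not pass (adjusted p = 0.132). With median centring in place of loess neither list passed (adjusted p = 0.377 for Hox and 0.0575 for housekeeping genes); over the alternatives their adjusted p ran from 0.0246 to 0.611 and from 0.0173 to 0.611.

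**Figure D2:**
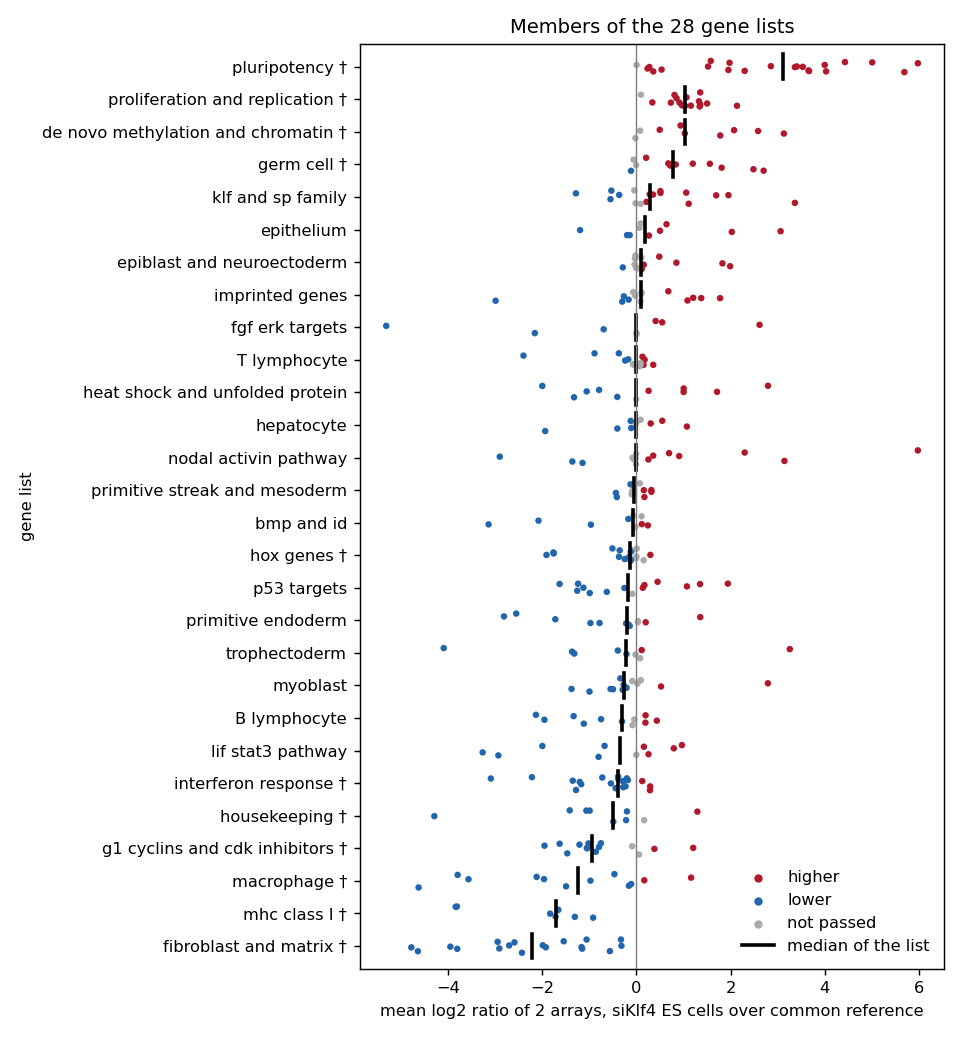
Mean log2 ratio of siKlf4 ES cells over the common reference on 2 arrays (x axis) for each measured member of the 28 gene lists (y axis), coloured by whether the gene was higher, lower or not passed; black lines are list medians, which run from -2.21 (fibroblast and matrix) to 3.11 (pluripotency). A dagger marks the 11 lists called with a preset correlation.

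Signalling genes around Klf4 and Lefty1 went both ways. In the Klf and Sp family, 10 of 17 were higher, 4 lower and 3 not passed at a median of 0.28, with Klf2, Klf5 and Klf9 (1.69) at the top and Klf6 lowest (-1.29; adjusted p = 0.14). In the Nodal and activin pathway, 7 of 15 were higher, 3 lower and 5 not passed. Tdgf1, Lefty1 and the ligand gene Gdf3 (2.30) were higher and Inhba, the activin A subunit gene, was lower (-2.90); the median was -0.01 and the mean 0.54, and the test pointed up (adjusted p = 0.353). Of 10 LIF and Stat3 pathway genes, 4 were higher, 5 lower and 1 not passed (1 of the higher was above the negative control spots in neither channel), with Cebpb at -3.27, Fos at -2.93, Jak1 at -2.00 and Pim3 at 0.97 (adjusted p = 0.514). FGF and Erk targets split into 3 higher, 3 lower and 2 not passed, with Etv5 at 2.62, Ier3 at -2.16 and Dusp6 at -0.70 beside Egr1; the median was 0.00, the mean -0.57, and the test pointed down (adjusted p = 0.877). In the BMP and Id list 2 were higher, 4 lower and 3 not passed, Id2 at -3.14 and Id3 at -2.08 being lowest, with Bmp2 at -0.17 and Smad6 at 0.11 (adjusted p = 0.331). Adjusted over the list alone, the counts of these 5 lists were the same. By fry, the Klf and Sp list (adjusted p = 0.0149) and the Nodal list (adjusted p = 0.0107) were called higher, and the LIF and BMP lists (both adjusted p = 0.0188) and the FGF list (adjusted p = 0.00462) lower.

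Lineage marker lists were not called by camera, and their members lay on both sides of the reference. Primitive endoderm genes were lower in 8 and higher in 2 of 12 cases, with 2 not passed, and Sparc stood at -2.55, Col4a1 at -1.72, Lama1 at 1.36 and Lamb1 at -0.78 (adjusted p = 0.116). Trophectoderm genes were lower in 5 and higher in 2 of 9 cases, with 2 not passed, and ranged from the keratin gene Krt18 (-4.09), Gata3 (-1.37) and Krt7 (-1.32) to Tfap2c (3.26; adjusted p = 0.301). In the primitive streak and mesoderm list, 4 of 12 were higher, 3 lower and 5 not passed (1 of the higher above the negative control spots in neither channel), with 0 at 2-fold in either direction and Mixl1 at -0.44, Tbx6 at -0.42, Cdx1 at 0.32 and Mesp2 at -0.13 (adjusted p = 0.937). No member of this list exceeded the largest absolute log2 ratio at a negative control spot, 0.52. Tbx6 in the ES cells and Cdx1 in the reference were above the negative control limit on only 1 array, so their ratios are uncertain. Epiblast and neuroectoderm genes were higher in 6 and lower in 1 of 13 cases, with 6 not passed, led by Otx2 (1.99), Tubb3 (1.83), Neurod1 (0.85) and Pou3f1 (0.49; adjusted p = 0.181), and 5 were higher adjusted over the list alone; with median centring in place of loess this list passed (adjusted p = 0.0469; range over the alternatives 0.0376 to 0.611). Imprinted genes were higher in 5 and lower in 4 of 14 cases (6 higher adjusted over the list alone), with 5 not passed and Dlk1 at -2.99, Phlda2 at 1.78, Impact at 1.38 and Cdkn1c at 1.21 (adjusted p = 0.502). The other 3 lists had the same counts adjusted over the list alone. By fry, the primitive endoderm and trophectoderm lists were called lower (both adjusted p = 0.0188) and the epiblast (adjusted p = 0.0376) and imprinted lists (adjusted p = 0.039) higher, but not the primitive streak list (adjusted p = 0.931).

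Markers of other cell types, among them types in the pool, and stress genes also split. Epithelial genes were higher in 5 and lower in 3 of 10 cases, with 2 not passed and the adherens junction gene Cdh1 at 3.06, Cldn4 at 2.03, Cldn3 at 0.64 and Krt19 at -1.20 (adjusted p = 0.226). B lymphocyte genes were lower in 6 and higher in 3 of 11 cases, with 2 not passed and Cd79b at -2.13, Blnk at -1.95, Ms4a1 at -1.33 and Pou2af1 at -1.12 (adjusted p = 0.14). T lymphocyte genes were lower in 5 and higher in 4 of 14 cases (1 of the higher above the negative control spots in neither channel), with 5 not passed and Lat at -2.40, Cd3g at -0.89, Lck at 0.36 and Zap70 at -0.24 (adjusted p = 0.735). Myoblast genes were lower in 8 and higher in 2 of 13 cases, with 3 not passed and Acta1 at -1.38, Myf5 at -0.55, Mylpf at 2.79 and Myl4 at 0.52 (adjusted p = 0.181). Hepatocyte genes were lower in 4 and higher in 3 of 10 cases, with 3 not passed and Ahsg at 1.07, Trf at 0.55, Apoa2 at -0.41 and Apoc3 at 0.30; the median was -0.005, the mean -0.06 and the test pointed up (adjusted p = 0.999). Targets of p53 were lower in 7 and higher in 6 of 14 cases, with 1 not passed and Trp53inp1 at 1.94, Cdkn1a at -1.63, Bax at 1.35 and Perp at -1.26 (adjusted p = 0.536). Heat shock and unfolded protein genes were higher in 5 and lower in 5 of 11 cases, with 1 not passed and Hspb1 at 2.79, Ddit3 at -1.33, Xbp1 at -1.06 and Hsph1 at 1.00; the median was -0.004, the mean 0.11 and the test pointed up (adjusted p = 0.999). Counts in these lists were the same adjusted over the list alone. By fry, the epithelial list was called higher (adjusted p = 0.0266), and the B lymphocyte (adjusted p = 0.0148), T lymphocyte and hepatocyte lists (both adjusted p = 0.0188) lower. It did not call the myoblast (adjusted p = 0.0952), p53 (adjusted p = 0.0745) or heat shock lists (adjusted p = 0.447).

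The arrays repeated each other closely, and few genes differed between them. Plat, the tissue plasminogen activator gene, differed most, at -1.42 on array 1 and 0.18 on array 2, a difference of 1.60 (0.46 without background correction and 2.10 with an offset of 10). Its ES signal was 157 and 184 units and its reference signal 262 and 63.6, so the difference lay in the reference spot. Cyp2c39 and Camk2a followed, but neither lay above the negative control spots in the reference on either array, nor Camk2a in the ES cells, so their ratios are not given. Baz2a (array 2 minus array 1, -0.57), St6galnac5 (-0.54) and Pigt (-0.54) were lower on array 2, and Arl6ip6 (0.56), Mzt1 (0.56) and Capza2 (0.53) higher. Without background correction these differences, apart from that of Pigt, were 0.20 to 0.30 in size. Cyp26a1, also among the 10 genes, was not above the negative control spots in either channel. Klf4 differed by 0.16, and 12.1% of probes differed by as much or more. The difference had an SD of 0.108 over 20795 probes, 2 of which differed by 2-fold or more, and log2 ratios correlated across probes at Pearson 0.987 and Spearman 0.953, probes not being independent replicates. Log2 ratios of the 162 negative control spots also correlated between arrays (Pearson 0.753), so a ratio that repeats can still be technical. With 1 array on each side no difference between the arrays could be tested.

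**Figure D3:**
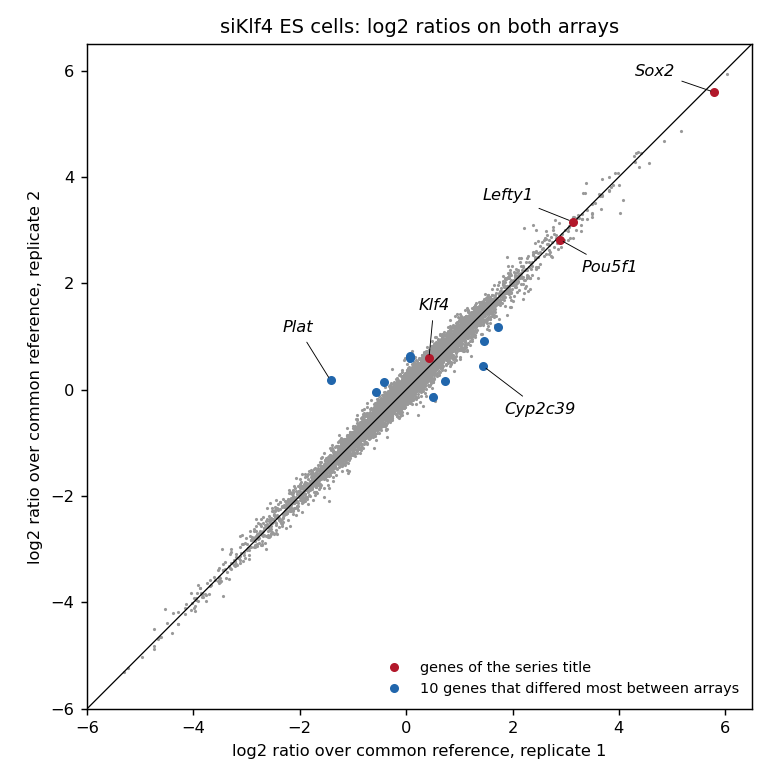
Log2 ratio of siKlf4 ES cells over the common reference on replicate 1 (x axis) and replicate 2 (y axis), 1 grey point per probe, with the genes of the series title in red, the 10 genes that differed most in blue and the line of equal values. Points follow the line (Pearson 0.987 across probes), with Plat (-1.42 and 0.18) farthest from it.

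The ES channel differed somewhat more between arrays than the reference channel, which held the same pool on both. The SD over probes was 0.190 in the ES channel and 0.167 in the reference channel, a ratio of 1.14. Among the 801 brightest probes the SDs were 0.132 and 0.0818, a ratio of 1.61. The channels also differ in dye, so these ratios do not separate cells from dye.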

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

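Settings based on the negative control spots or on the position on the array, and the housekeeping list without Hprt, were chosen after the data were seen. No call past the threshold reversed, but medians of lists not called changed sign, such as those of the Nodal (-0.02 to 0.14), FGF (-0.17 to 0.03), heat shock (-0.19 to 0.13) and imprinted lists (-0.02 to 0.11). The balance of higher and lower probes depended on the scaling, with 849 at least 2-fold higher and 1245 lower with median centring, and 6077 higher and 6580 lower at any size with the trend over brightness and position removed. Among the 127 named genes, 1887 of 1900 comparisons with an alternative kept direction and side of the threshold and 13 lost the threshold, at genes with small ratios such as Smad6, Bmp2, Zap70 and Lck. These counts, and those of the lists below, overstate the stability. Leaving out the flag filter, which removed 0 probes, could change nothing, and the series table carries the same ratios as the processed signals. Most of these genes were also named for large ratios in the same data. Klf4 ranged from 0.31 with median centring to 0.55 with the trend over brightness and position removed. Sizes moved more: without background correction the fold of 60 named genes above the negative control limits in both channels changed by more than 1.5 times, each toward 0, and with an offset of 10 that of 2 genes, among them Tfap2c (3.93). List medians moved by as much at pluripotency (1.86), fibroblast and matrix (-1.12), MHC class I (-0.74) and G1 genes (-0.32) without background correction, and at macrophage markers (-1.82) with background from the negative control spots. Of 449 comparisons of the 28 lists, 412 were unchanged, 23 lost and 14 gained a call. Without background correction, 469 probes were at least 2-fold higher and 440 at least 2-fold lower, and the SD of the difference between arrays was 0.0616; this setting leaves the scanner offset in both channels, which draws ratios toward 0. Camera with an estimated correlation, which has very little power at 1 residual degree of freedom, called 0 lists higher and 0 lower. By contrast fry, which does not compare a list with other genes, called 9 and 15. With log2 ratios larger than at any negative control spot required, 2552 probes were higher and 2273 lower, fewer by construction. Each array alone, a value with no test, gave 1041 to 1117 probes at least 2-fold higher and 1079 to 1121 lower. Counts by adjusted p and list calls have no value on 1 array, since no residual degrees of freedom remain. The difference between arrays of Plat ranged from 0.46 (no background correction) to 2.10 (offset of 10); of the 10 genes that differed most, 9 and 5 moved by more than 1 SD under these settings, 4 with background from the negative control spots and 2 with median centring, and 0 reversed. The housekeeping call was lost under no background correction (adjusted p = 0.0538), an offset of 10 (0.0596), median centring (0.0575), negative-control filters in the same channel (0.0641) and in both (0.121), without Hprt (0.132) and with the trend over brightness and position removed (0.0927). The Hox call was lost under no background correction (0.0538), median centring (0.377) and the same filters (0.0704 and 0.121). In the list without Hprt, that gene carried the call. The filter in both channels also left Hprt out of the housekeeping list, whose median was -0.36, as in the list without Hprt. For the other losses the cause was not tested. No paired analysis was possible because the samples form only 1 group. Signal over background limits the dim end: 85.2% and 82.7% of probes lay above the negative control limit in the ES channel, and 91.6% and 87.4% in the reference.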

Other observations

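Genes were also picked, after the values were seen, from the 20 genes that follow the 10 highest and the 20 that follow the 10 lowest; they stand for no tested group. Dppa3 (3.66) and Ooep (3.84), both maternal-effect genes, Dppa4 (3.53), the X-linked Rhox5 (3.31) and Trap1a (3.66), and the transcription factor genes Tcf15 (3.87) and Mycn (3.53) were among the next 20 highest. Tdh (3.41), the threonine dehydrogenase of mouse ES cells, stood beside Gldc of the same glycine route, and Slc2a3 (3.30) encodes a glucose transporter. Apoe (3.77), Fabp3 (3.19) and the prohormone gene Trh (3.39) were there too.

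At the low end, the next 20 genes held the annexin genes Anxa3 (-4.33) and Anxa1 (-4.19), the C/EBP factor gene Cebpd (-3.87), the signalling regulator Rgs2 (-4.08) and Nfix (-3.84), a factor of later development. The chemokine genes Cxcl12 and Pf4 stood at -3.66 and -3.80 and the collagen gene Col16a1 at -3.95. The actin-severing protein gene Gsn stood at -3.69 and the detoxifying enzyme gene Ugt1a6a at -3.93.

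All tests in the following paragraphs were chosen after the results were seen. Negative control spots, which carry no mouse sequence, had log2 ratios away from 0 (median 0.16, SD 0.14, 115 of 162 past the p threshold). With background taken from these spots, their median was still 0.0986 (SD 0.10), and 62 passed, so that setting did not remove the pattern. The SE of 0.0080 treats the spots as independent, which they are not, since their ratios followed the column on the array. The later loess, fitted on gene probes, can also move these spots. Whether background left in 1 channel is the whole cause therefore stays undecided. A trend across the array is a candidate explanation, since their ratios correlated with the column at r = 0.756. The count past the threshold was 32 once a trend over brightness and position was removed, a setting that does not separate position from brightness. Among the 5257 brightest gene probes the trend had the opposite sign (median 0.36 at the lowest and -0.06 at the highest columns, against -0.10 and 0.15 among the 5257 dimmest), and no biological explanation was tested.

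Where a gene had a pair of probes (181 genes), the difference between arrays was shared by them, with r = 0.553 across genes, which are not independent replicates (permutation p = 1e-04, the smallest that 10000 permutations can give; highest random pairing 0.353). Noise of single spots would leave no such correlation. Smooth trends over ratio, brightness or position are argued against as well, since r was 0.548 after they were removed. A difference between the ES cell cultures may be the source, but the single channels show it only weakly. In the ES channel alone r was 0.251 (permutation p = 0.001), below the highest random pairing there, 0.294. In the reference channel r was 0.0636 (permutation p = 0.391). A culture difference cannot be told apart from a difference in labelling of the ES cell RNA, because the labels do not say whether the arrays hold separate cultures or 1 RNA labelled for each.

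Hprt stood at the level of the negative control spots in the ES cells, at 154 and 193 units against limits of 155 and 178. A probe that does not hybridise is argued against by its reference signal of 2736 and 2823 units. Against low transcript levels across that stretch of the X chromosome stand the ratios of its measured neighbours, Phf6 (-0.33) and Plac1 (-0.21). This argument is weak, since a gene low in both channels also has a ratio near 0. Their ES signals were 316 and 367 units (Phf6) and 370 and 379 (Plac1), near those of the median gene probe (308 and 355). EB5 cells derive from an ES cell line deficient in Hprt, so an Hprt gene without transcript may be the reason. That cannot be told apart from a very low level: on array 1, 9 negative control spots were as bright as Hprt, whereas on array 2 it exceeded 161 of 162.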
